A study of Mus musculus with 6 samples.

How the data were processed

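Whole pancreas of 1-day-old mice was profiled by bulk RNA-seq, with 3 WT and 3 miR-216a null (KO) libraries, each from its own mouse per the labels. Groups were taken from the genotype label, and replicate numbers follow sample order only, so they pair no samples. Per the labels' protocols, RNA was isolated with a method adapted to pancreas, checked on a Bioanalyzer and prepared with a stranded mRNA kit. Sex, litter and sequencing batch are not given in the sources used here.

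Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and processed with Salmon 0.13.1 and DESeq2 1.24.0, with the build mm10. For each library the authors deposited Salmon's table of 116248 transcripts, whose estimated counts per transcript are not whole numbers and were not normalized. The TPM values the authors deposited beside them were not used. Salmon's effective lengths, per the file headers, entered 1 alternative only. The authors also deposited a table of 17324 genes for the whole series, which holds a scaled signal and not counts. Between 0.57 and 0.79% of its values were whole, and its ratio to the summed reads followed the inverse of each library's size factor (0.882 to 1.10 against 0.870 to 1.11). The plan had taken that table for counts, so the input of the main test was changed to the summed estimated counts before any test was run.

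The transcript set that Salmon used is not given in the sources used here. Of the transcripts listed, 115995 matched GENCODE M21 (GRCm38) by versioned identifier, all with equal length. The rest held 0.034 to 0.046% of the reads and were left out. Estimated counts were summed to 35527 genes with Python 3.11.15 and pandas 2.3.3 and rounded to whole numbers. Depth was 20889909, 22922738 and 22491960 estimated reads in WT 1 to 3 and 20565387, 21401039 and 23028718 in KO 1 to 3. Every pair of libraries differed far beyond sampling noise, with a chi-square per degree of freedom from 22.6 to 86.8, so each was counted as its own sample. The biological coefficient of variation was 18.4%.

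The main test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3, with TMM normalization and filterByExpr's default filter, which kept 15805 genes. Benjamini-Hochberg adjusted p-values under 0.05 were called. CPM values are normalized by TMM, and errors are SDs over 3 libraries. With 3 against 3 libraries the smallest two-sided p of an exact permutation test is 0.1. Before the data were examined, 28 gene lists were fixed: acinar digestive enzymes, acinar secretory and zymogen granule, beta cell, alpha, delta, PP and epsilon cell, pan-endocrine, endocrine progenitor, ductal, mesenchyme and extracellular matrix, mesothelium, endothelium, macrophage and myeloid, lymphocyte, erythroid, nerve and glia, adipocyte, intestine and liver, S phase, G2 and M phase, cell cycle inhibitors and p53, TGF-beta and SMAD, PI3K and MTOR, reported miR-216a targets, unfolded protein response, acinar injury and acute phase, immediate early and heat shock, cholesterol synthesis, mitochondrially encoded and sex-linked genes. The sex-linked list is given as values, and the other 27 were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 27 lists. Each list's members were also adjusted over the list alone. Some genes stand in more than 1 list.

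Named genes were fixed by a rule written before the data were examined. It took up to 8 called genes per direction with the largest fold change, a mean of at least 1 CPM and no overlap between groups, of which there were 0. It also took up to 3 called members of each list or, where none was called, the 2 with the smallest p, as values only. Genes of the miR-216a locus, Smad7, Ins1, Ins2, Gcg, Sst, Amy2a5, Cpa1 and Mki67 were always named. Some genes that the rule takes are not reported here. Further members named as adjusted over the list alone, and libraries' Alb and Ddx3y values, were chosen after the values were seen.

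For the seed-site test the longest annotated 3' UTR of 20989 genes was searched for 8mer, 7mer-m8 and 7mer-A1 sites of miR-216a-5p. The difference in median log2 fold change between genes with and without a site was set against all other heptamers of the same base composition. Genes without an annotated 3' UTR were not searched.

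Settings varied were DESeq2's size factors, upper-quartile factors, leaving out the enzyme genes, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a transcript length offset, leaving out each library, camera with an estimated correlation, fry, and for the seed test fewer site types or genes above the median expression. Chosen after seeing the data were the authors' scaled table with limma on log2(value + 1), leaving out the erythroid-rich pair WT 1 and KO 2, and the erythroid level as a covariate. Before use, edgeR, DESeq2 and limma-voom were tested on simulated data with 200 changed genes, camera with its preset correlation on 1 planted list of 30 genes, and the seed-site test on a shift planted in 2543 genes. Camera with an estimated correlation and fry were tested on that planted list only after their results were seen, and called it at adjusted p = 0.0315 (camera), 0.00984 (fry, one direction) and 0.00131 (fry, either direction). Of 200 unchanged random lists, fry for either direction called 5 and the other list tests 0. Every simulated gene was drawn independently, so the list tests were not tried on lists whose genes vary together. DESeq2 gave no adjusted p for 1860 genes, which were left out of its counts. Figures were drawn with matplotlib 3.10.9.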

Results

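RNA from the whole pancreas of 6 newborn C57BL/6 mice was sequenced at day 1 after birth with a stranded mRNA kit. Wild-type (WT) mice gave 3 libraries, and mice lacking miR-216a, here called KO, gave the other 3. Each library came from its own donor mouse. Depth was even, between 20565387 and 23028718 estimated reads per library, and 15805 genes had enough reads to be tested. Digestive enzyme genes took 38.7 ± 3.75% of the counts in WT and 40.5 ± 2.58% in KO (SD, n = 3, exact permutation p = 0.6, two-sided). Amy2a5, a pancreatic amylase gene, alone held 10.04% of all counts, and the chymotrypsinogen gene Ctrb1 held 8.21%.

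The targeted gene was the first item to look at, because it checks the labels. Mir216a lies on chromosome 11 from 28757012 to 28757083 on the plus strand (GRCm38), inside the noncoding transcript Gm12082, which spans 28751633 to 28815767. Mir217, from 28763728 to 28763835, lies within that transcript too, while Mir216b (28746191 to 28746276) and Mir216c (28746198 to 28746266) lie before its start. The set of transcripts that was quantified held 0 transcripts of these 5 genes, so the loss of miR-216a was not analysed here and the genotypes rest on the labels.

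The libraries also differed in several ways, not all of which followed genotype. Erythroid genes took 0.605% of the counts in WT 1 and 0.449% in KO 2, against 0.177 to 0.298% in the other 4 libraries. Alb, the liver's albumin gene, stood at 219 CPM (read counts scaled to library size) in WT 1 and between 6.41 and 15.1 CPM elsewhere. Ddx3y, a Y-linked gene, stood at 0.141 CPM in KO 1 and between 61.8 and 102 CPM in the other 5 libraries. Of the other Y-linked genes, Eif2s3y was at 0 CPM in KO 1 and Kdm5d at 2.83 CPM there, against 27.1 to 36.6 CPM elsewhere. Sex is not labelled, but by these low Y-linked values KO 1 probably differs in sex from the other 5 libraries. The groups may therefore be unbalanced for sex. The first principal component held 31.3% of the variance, and every WT library lay at its negative end, from -26.1 to -17.3, with KO 1 at -1.9, KO 2 at 13.2 and KO 3 at 53.5. The second, with 26.4%, set KO 2 (46.0) and WT 1 (18.9) apart from the other 4 libraries, which lay between -25.2 and -3.0.

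The comparison of KO with WT asks which genes of the newborn pancreas differ when miR-216a is missing. The series title names proliferation and the function of endocrine and exocrine cells. Gm5771, a trypsinogen-like gene, had the smallest p, at 2478 ± 51.0 CPM in KO and 5848 ± 613 CPM in WT (SD, n = 3, log2 fold change -1.24 ± 0.13 SE). With edgeR's quasi-likelihood test, 0 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.205. Without adjustment, 1996 genes had p under 0.05, 889 of them higher and 1107 lower in KO, where 790 would be expected by chance. DESeq2 called 132 genes higher and 304 lower, and limma-voom called 1 in each direction. For 1433 genes every KO library lay above every WT library, and for 1630 every KO library lay below. Together these were 19.4% of the tested genes, against 10% by chance on average. Genes vary together, so 1 grouping can lie far from such an average, or from the 790, without a group effect. On simulated data, edgeR recovered 52.2% of genes changed by a factor of 2 with 7.8% false calls, and DESeq2 recovered 74.6% with 18.4% false calls. Without KO 1, edgeR called 87 genes higher and 275 lower. Whether the low Y-linked values of KO 1 have a part in this was not tested.

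Genes of the cell cycle were lower in KO. All 30 S phase genes and all 35 genes of G2 and M phase had a lower mean in KO. For 30 of 30 and 34 of 35 genes every KO library lay below every WT library. The estimated correlation between genes of a list was 0.842 for S phase and 0.893 for G2 and M. Counts of genes in these lists are therefore not counts of independent observations. Mki67, the proliferation marker Ki-67, stood at 137 ± 70.2 CPM in KO and 288 ± 38.4 CPM in WT. Ccne1, which encodes cyclin E1, stood at 6.54 ± 1.90 against 16.7 ± 0.991 CPM, and Cdk1, the mitotic kinase, at 22.3 ± 10.1 against 53.4 ± 8.52 CPM. Mybl2, a transcription factor of cycling cells, stood at 7.60 ± 3.31 against 19.6 ± 0.796 CPM, and Gins2, part of the replicative helicase, at 9.13 ± 2.08 against 18.4 ± 2.33 CPM. The median log2 fold change was -0.92 for the S phase list and -1.25 for the G2 and M list. Relative to the WT mean, the S phase median was -0.55 in KO 1, -0.79 in KO 2 and -1.52 in KO 3, and the G2 and M median was -0.49, -1.70 and -1.96. Adjusted over the list alone, 30 S phase genes and 34 genes of G2 and M fell in the edgeR test, against 0 and 0 adjusted over all genes tested. Anln was the exception. Both lists were called lower by camera with its preset correlation, at an adjusted p of 2.31e-44 and 6.27e-43, and lost the call at adjusted p = 0.367 for both with an estimated correlation. Without WT 3, or without KO 2, the count of G2 and M genes adjusted over the list alone was 0, and the list's median was -1.13 and -1.05. Erythroid genes took 0.390 ± 0.187% of the counts in WT and 0.270 ± 0.155% in KO (SD, n = 3, exact permutation p = 0.5, two-sided).

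**Figure D1:**
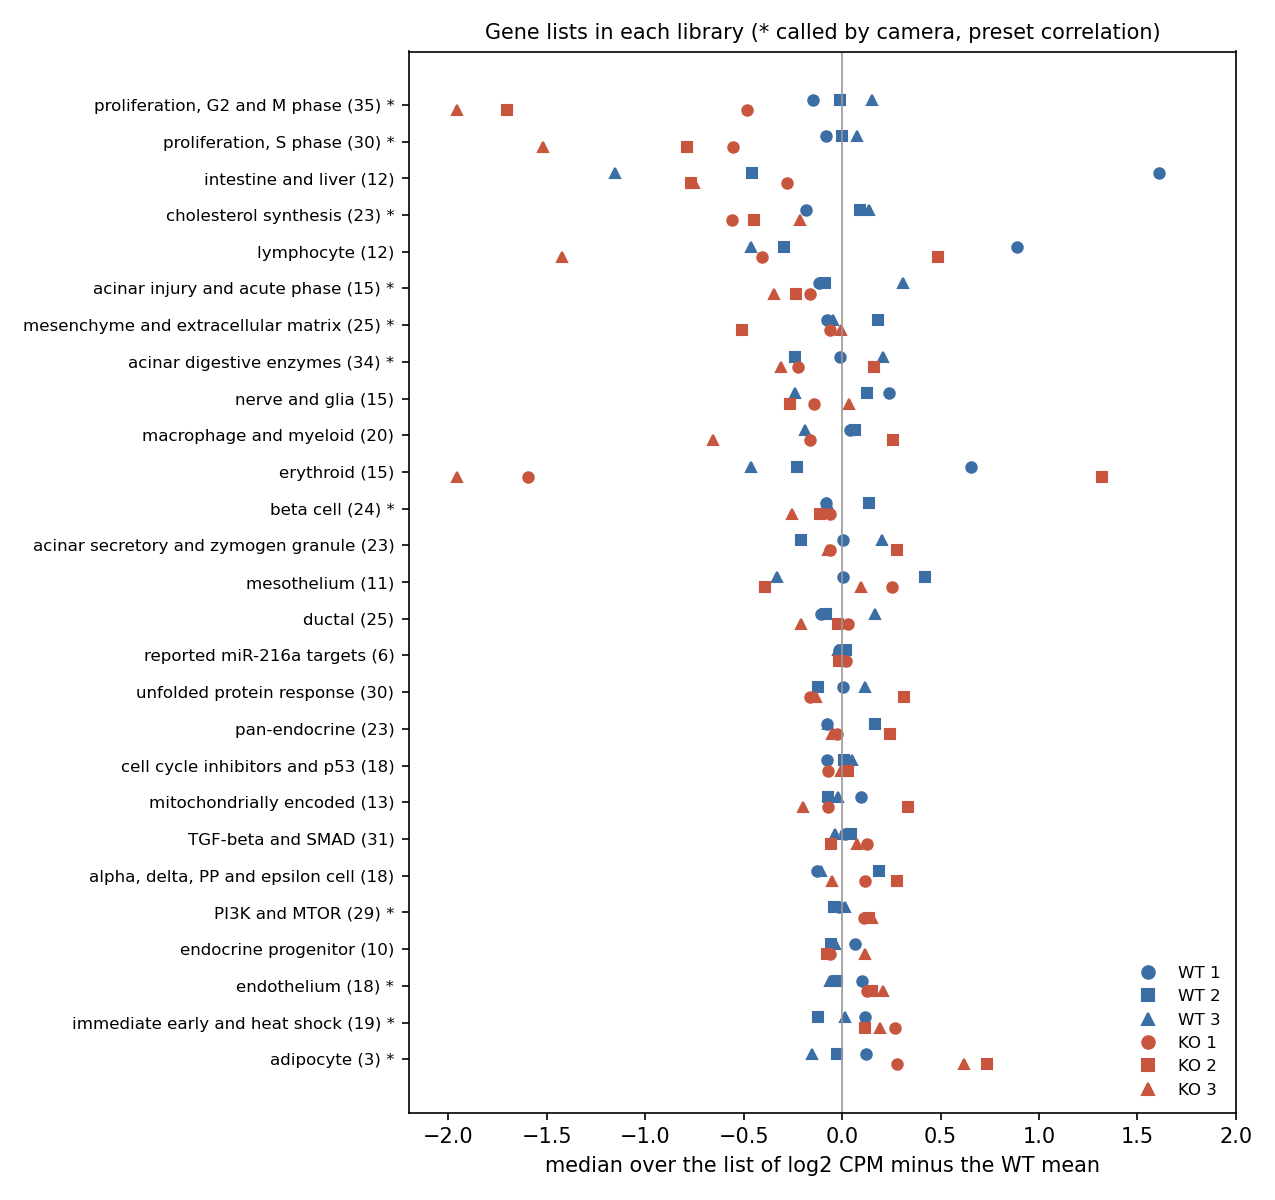
For each gene list, the horizontal axis gives each library's median over the list of log2 CPM minus the WT mean, with the number of measured genes in brackets. Circles, squares and triangles mark replicates 1, 2 and 3 (blue WT, red KO), and the 3 KO libraries lie between -0.49 and -1.96 for the G2 and M list and between -0.55 and -1.52 for the S phase list.

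The list of cell cycle inhibitors and p53 genes was not called (camera adjusted p = 0.826, 18 genes, median log2 fold change 0.04, mean -0.08, so the median and the test differ in sign). Its members with the smallest p were Gtse1, a gene of G2 and M phase, at 4.59 ± 2.84 CPM in KO and 10.6 ± 2.28 CPM in WT, and Cdkn2c, an inhibitor of CDK4 and CDK6, at 9.58 ± 4.71 and 18.8 ± 2.11 CPM.

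Insulin genes and other beta cell genes were lower in KO, while glucagon was level. Ins1 stood at 1700 ± 169 CPM in KO and 2245 ± 253 CPM in WT, and Ins2 at 2206 ± 87.2 against 3027 ± 301 CPM, with every KO library below every WT library for both. Mafa, a transcription factor of mature beta cells, stood at 10.9 ± 1.80 against 18.2 ± 2.39 CPM, and G6pc2, the islet glucose-6-phosphatase subunit, at 37.6 ± 9.79 against 65.1 ± 3.36 CPM. Of 24 beta cell genes, 15 were lower and 9 higher. Adjusted over the list alone, G6pc2, Mafa and Ins2 fell, 3 in all, against 0 adjusted over all genes. The list was called lower by camera (adjusted p = 0.0382, median log2 fold change -0.08), with adjusted p = 0.874 with an estimated correlation. The call was also lost without WT 2 (adjusted p = 0.478) and without KO 3 (0.394). In fry's test for change in either direction the beta cell list had an adjusted p of 0.0313. On simulated data that test also called 5 of 200 unchanged random lists.

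The other endocrine lists were not called. Gcg, which encodes glucagon, stood at 1429 ± 418 CPM in KO and 1400 ± 300.2 CPM in WT. Sst, the delta cell hormone somatostatin, stood at 107 ± 23.3 against 148 ± 15.5 CPM, and Slc7a2, a transporter of cationic amino acids, at 113 ± 22.8 against 76.7 ± 5.44 CPM. The list of alpha, delta, PP and epsilon cell genes had an adjusted p of 0.357 and a median log2 fold change of 0.08, but without WT 2 it was called higher (0.0191). The pan-endocrine list, at 0.912, had Pcsk1n (54.0 ± 7.42 against 72.6 ± 15.3 CPM) and Ptprn (24.0 ± 2.99 against 30.4 ± 4.86 CPM) as its members with the smallest p. The endocrine progenitor list, at 0.470, had Amotl2 (54.7 ± 10.8 against 40.0 ± 4.02 CPM) and Tox3 (18.6 ± 2.19 against 14.1 ± 2.25 CPM).

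**Figure D2:**
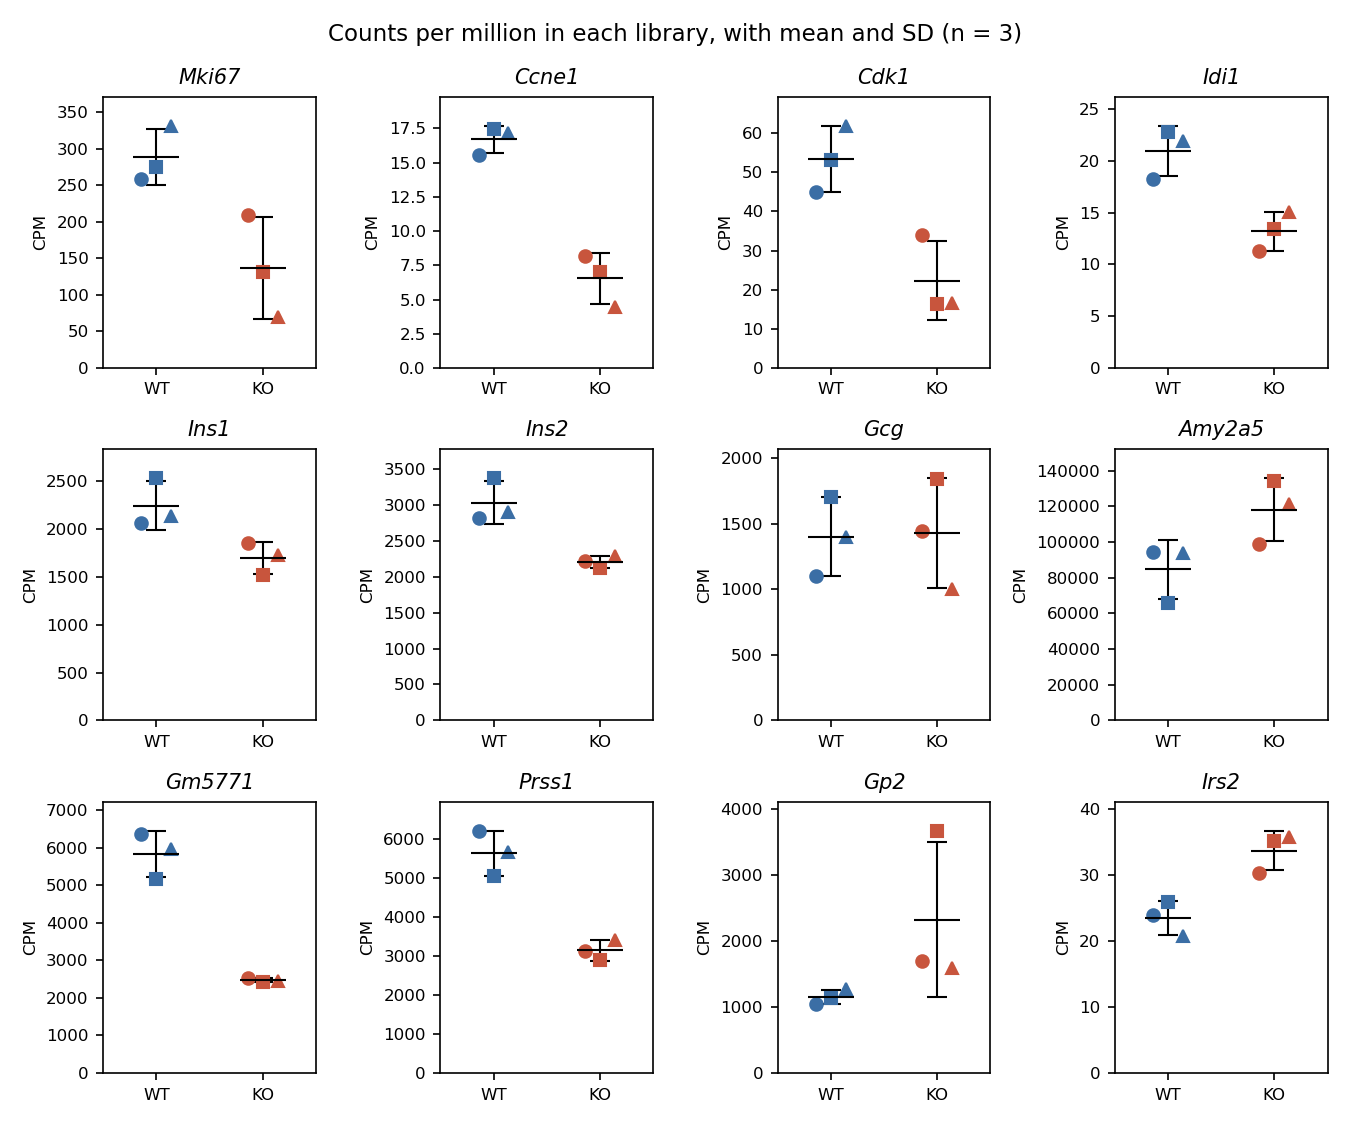
CPM values (vertical axes, from 0) of 12 genes in each WT (blue) and KO (red) library, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD of 3 libraries. Ins1, Ins2, Mki67, Ccne1, Cdk1, Idi1, Gm5771 and Prss1 have every KO library below every WT library, Amy2a5, Gp2 and Irs2 have every KO library above, and Gcg overlaps.

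In the exocrine pancreas, all 12 measured trypsinogen genes of the cluster on chromosome 6, grouped after gene-level results were seen, had a lower mean in KO. Of the 23 digestive enzyme genes outside the cluster, 8 were lower and 15 higher. Prss1, which encodes a trypsinogen, stood at 3150 ± 263 CPM in KO and 5645 ± 579 CPM in WT. Amy2a5 stood at 118100 ± 17660 CPM in KO and 84560 ± 16480 CPM in WT, and Cpa1, which encodes carboxypeptidase A1, at 10120 ± 1656 and 9684 ± 1367 CPM. Cel, an abundant lipase gene chosen after its values were seen, stood at 10860 ± 826 CPM in KO and 14060 ± 2494 CPM in WT, with every KO library below every WT library. Try5, the most abundant trypsinogen gene and likewise chosen after, stood at 23870 ± 6679 and 25190 ± 3394 CPM. Of 34 enzyme genes, 19 were lower and 15 higher. Adjusted over the list alone, Gm5771, Prss1, 1810009J06Rik and Prss3 fell, 4 in all and each from that cluster, against 0 adjusted over all genes. Single values of these near-identical genes are uncertain, because Salmon divides the reads they share. The list was called lower by camera (adjusted p = 0.00854, median log2 fold change -0.15), with adjusted p = 0.874 with an estimated correlation. The call was lost without WT 3, where the median turned to 0.02 (adjusted p = 0.479), without KO 1 (0.533) and without KO 3 (0.0648). Fry's test for change in either direction gave an adjusted p of 0.000152. It called 2 of the 27 lists, this one and the beta cell list, and not S phase (0.0729) or G2 and M phase (0.0990).

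Tmed11, a cargo receptor gene of the secretory pathway, was 5.13 times as high in KO (78.3 ± 45.7 against 15.2 ± 0.369 CPM), and was the 1 secretory and zymogen granule gene that rose adjusted over the list alone, with 0 adjusted over all genes. Gp2, the main membrane glycoprotein of zymogen granules, stood at 2322 ± 1172 against 1152 ± 112 CPM. That list was not called (adjusted p = 0.319, 23 genes, median log2 fold change 0.01, or -0.01 with upper-quartile scaling). It was called higher without WT 3 (0.0104) and without KO 1 (0.0229). Reg3b, a secreted lectin induced in injured acinar tissue, stood at 37.4 ± 13.7 CPM in KO and 300 ± 208 CPM in WT, where WT 1 had 63.8 CPM and WT 2 and WT 3 had 376 and 459 CPM. Reg3a stood at 1.05 ± 0.360 against 6.24 ± 3.88 CPM. Of the 15 genes of acinar injury and acute phase, Reg3b, Reg3a, Reg3g and Tff2 fell and Nupr1 rose adjusted over the list alone, with 0 adjusted over all genes. The list was called lower (camera adjusted p = 0.0485), with adjusted p = 0.468 with an estimated correlation, and the call was lost without WT 3 and without each KO library in turn (0.0968 to 0.217).

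Sterol synthesis genes were lower in KO. Of 23 genes, 22 had a lower mean, but the estimated correlation between them was 0.465, so they are not independent observations. Relative to the WT mean, the list's median was -0.56 in KO 1, -0.45 in KO 2 and -0.21 in KO 3. In WT 1 it was -0.18, nearly level with KO 3, and in WT 2 and WT 3 it was 0.09 and 0.13. Idi1, which encodes an isomerase of isopentenyl diphosphate, stood at 13.2 ± 1.88 CPM in KO and 20.98 ± 2.41 CPM in WT. Adjusted over the list alone, 6 genes fell, among them Idi1, Cyp51, Stard4 and Sqle, against 0 adjusted over all genes. The list was called lower by camera (adjusted p = 2.48e-08, median log2 fold change -0.35), with adjusted p = 0.468 with an estimated correlation.

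Genes of insulin receptor and PI3K signalling were slightly higher in KO. Insr, the insulin receptor, stood at 66.3 ± 2.20 CPM in KO and 50.4 ± 4.03 CPM in WT, and Irs2, its adaptor, at 33.7 ± 3.03 against 23.5 ± 2.60 CPM. Both rose adjusted over the list alone, against 0 adjusted over all genes, and 23 of 29 members were higher. The list was called higher by camera (adjusted p = 0.00476, median log2 fold change 0.10), with adjusted p = 0.367 with an estimated correlation. The TGF-beta and SMAD list was not called (0.319, median 0.05). It was called higher without KO 2 (0.0310). Its members with the smallest p were Tgfbr3, at 87.7 ± 25.4 against 60.8 ± 10.4 CPM, and Inhbb, at 4.77 ± 1.75 against 3.07 ± 0.0701 CPM.

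Among stress genes, the immediate early and heat shock list was called higher (adjusted p = 0.0244, median log2 fold change 0.19, 12 of 19 genes higher), with adjusted p = 0.674 with an estimated correlation. Dusp1, a MAP kinase phosphatase, stood at 15.5 ± 1.25 CPM in KO and 10.1 ± 1.74 CPM in WT, and the small heat shock gene Hspb1 at 26.2 ± 4.16 against 19.9 ± 2.68 CPM. The call was lost without WT 2 (0.179) and without KO 1 (0.217). The unfolded protein response list was not called (0.319, median 0.03). Eif2ak3, the stress kinase PERK, stood at 91.7 ± 0.810 against 62.2 ± 11.9 CPM, and Chac1 at 6.07 ± 2.19 against 2.70 ± 1.16 CPM. Without KO 2 that list was called lower (0.0315), and without WT 3 (0.0437) or KO 1 (0.0166) it was called higher. Mitochondrially encoded genes had an adjusted p of 0.514 and a median of 0.04, with mt-Co1 at 6147 ± 1029 against 5277 ± 350.5 CPM and mt-Nd6 at 26.1 ± 8.44 against 21.9 ± 5.86 CPM.

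Among markers of other cell types, endothelial and adipocyte genes were called higher in KO, and mesenchyme and matrix genes lower. Endothelial genes were called higher in KO (adjusted p = 0.00667, median log2 fold change 0.16, 16 of 18 genes higher), with adjusted p = 0.468 with an estimated correlation. Flt1 and Kdr, receptors for VEGF, stood at 73.0 ± 12.8 against 54.8 ± 8.04 CPM and 133 ± 12.1 against 108 ± 12.6 CPM. The adipocyte list was called higher (0.00854, median 0.49), with adjusted p = 0.367 with an estimated correlation. Only 3 of its 12 genes were measured, so the call does not speak for most of the listed fat cell markers. Fabp4, a fatty acid carrier of fat and capillary endothelium, stood at 84.8 ± 31.7 against 41.6 ± 6.33 CPM and rose adjusted over the list alone, with 0 adjusted over all genes. Pparg stood at 3.25 ± 0.218 against 2.31 ± 0.541 CPM, and for both genes every KO library lay above every WT library. Mesenchyme and matrix genes were called lower (0.0273, median -0.22), with adjusted p = 0.874 with an estimated correlation, and the call was lost without WT 2 (0.357) and without KO 2 (0.794). Col6a3 stood at 237 ± 38.8 against 325 ± 39.0 CPM and Pdgfra at 125 ± 14.6 against 95.3 ± 2.67 CPM.

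The remaining cell type lists were not called. Erythroid genes had an adjusted p of 0.139, with Hba-a2 at 1046 ± 591 against 1552 ± 772 CPM and Hbb-bt at 234 ± 162 against 333 ± 153 CPM. Macrophage and myeloid genes had 0.139, with C1qa at 49.2 ± 2.73 against 58.5 ± 5.95 CPM and Fcer1g at 16.6 ± 2.10 against 18.1 ± 2.65 CPM. Lymphocyte genes had 0.346, with Cd3e and Rag1 under 1 CPM on average in both groups. Nerve and glia genes had 0.334, with Gap43 at 8.68 ± 1.35 against 12.8 ± 1.57 CPM and Cdh19 at 2.18 ± 0.931 against 1.13 ± 0.145 CPM. Ductal genes had 0.912, with Dcdc2a at 67.8 ± 5.14 against 55.0 ± 2.58 CPM and Ambp at 74.7 ± 3.14 against 95.1 ± 14.4 CPM. Mesothelial genes had 0.939, with Nkain4 at 13.0 ± 1.502 against 11.2 ± 2.31 CPM and Igfbp5 at 360 ± 36.1 against 409 ± 83.8 CPM. For the ductal and mesothelial lists the median, 0.01 in both, was positive where the mean was negative, and the median changed sign with upper-quartile scaling. Intestine and liver genes had 0.912. Lgals4, an intestinal galectin, stood at 19.3 ± 3.90 against 8.55 ± 0.737 CPM and was the 1 member that rose adjusted over the list alone, with 0 adjusted over all genes. Without WT 3 or without KO 2, the macrophage, lymphocyte and erythroid lists were called lower in KO, and without WT 3 the nerve and glia list was too. Without WT 2, the mesothelial list was called higher.

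The seed-site test asks whether genes that miR-216a could bind directly differ from the rest. Smad7, an inhibitor of TGF-beta signalling that carries a site in the 3' UTR, stood at 10.6 ± 2.02 CPM in KO and 10.5 ± 0.358 CPM in WT. Ybx1, an RNA-binding protein gene that also carries a site, fell adjusted over the list alone, from 285 ± 15.9 CPM in WT to 229 ± 9.24 CPM in KO, with 0 adjusted over all genes. The list of 6 reported targets was not called (camera adjusted p = 0.912, median log2 fold change 0.02, which turned to -0.00 with upper-quartile scaling, and mean -0.01). Of these 6 genes, Becn1 and Cdc42 held no site in the searched 3' UTR. Across 15805 tested genes, the 2564 with a site for the miR-216a-5p seed TGAGATT had a median log2 fold change 0.045 above that of the 12516 searched genes without one. This difference stood at the 82.8th percentile of 209 other heptamers of the same base composition, which ranged from 0.020 to 0.052 (permutation p = 0.319, two-sided). The neighbouring miR-216b-5p and miR-217-5p gave differences of 0.041 (p = 0.70) and 0.037 (p = 0.652), by the same permutation of heptamers. On simulated data the same permutation of heptamers detected a planted shift of 0.02 (p = 0.019). There the shift was added to every gene with a site, after the fit, and genes were drawn independently. The simulation therefore does not show what the test would detect if only some site genes changed or if genes vary together.

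**Figure D3:**
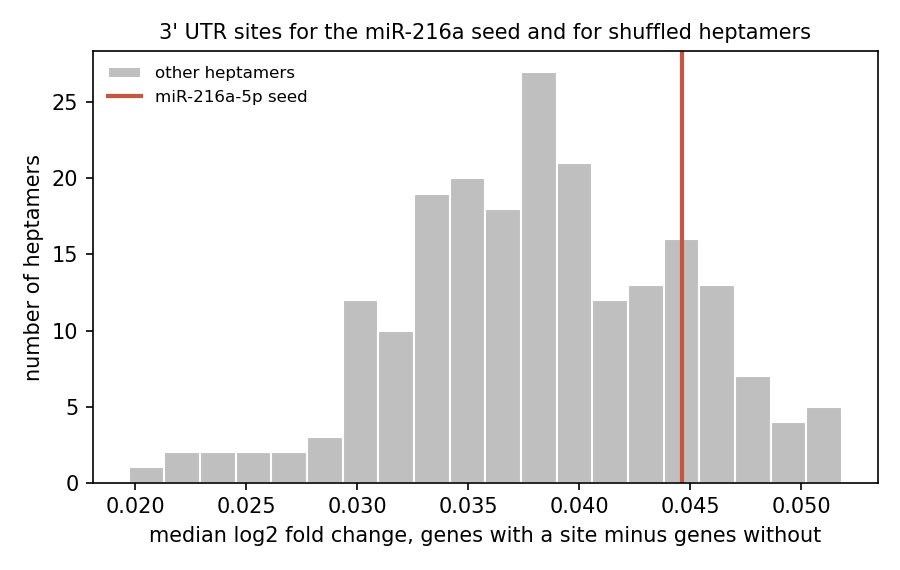
The histogram counts heptamers with the same bases as the miR-216a-5p seed (vertical axis) by the median log2 fold change of genes with a 3' UTR site minus that of genes without (horizontal axis). The red line at 0.045 is the miR-216a-5p seed, inside the range of the 209 others, 0.020 to 0.052.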

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

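The erythroid-rich pair (WT 1 and KO 2) left out, the erythroid covariate and the authors' scaled table were chosen after the data were seen, and the other alternatives were planned. Of the 11 called lists, 6 stayed called in the same direction in all 17 refits: S phase, G2 and M phase, cholesterol synthesis, PI3K, endothelium and adipocyte. The adipocyte list held 3 of its 12 genes in the main test. None of the 11 was called by camera with an estimated correlation or by fry's directional test. The S phase median ran from -1.08 to -0.71 over the refits and the G2 and M median from -1.81 to -0.97. The seed-site difference ran from 0.034 to 0.049 (p from 0.214 to 0.867) and was never called. Where a value below changed its call, the cause was not tested unless stated.

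Genes called higher and lower numbered 132 and 304 with DESeq2 and 1 and 1 with limma-voom. Without a filter 1 gene was called lower, and without the erythroid-rich pair 1 and 1 were called. Over the leave-outs the counts ran from 0 to 87 higher and from 0 to 275 lower, highest without KO 1. Of 63 named genes, DESeq2 called 26 and the fit without KO 1 called 13. Called lists numbered 0 with an estimated correlation, 0 with fry and 7 in the authors' scaled table. The G2 and M genes called over the list alone numbered 0 without the erythroid-rich pair, where fewer samples were tested, and from 0 to 35 over the leave-outs.

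Adjusted p-values with an estimated correlation were 0.367 for S phase, G2 and M phase, PI3K and adipocyte, 0.468 for endothelium, cholesterol synthesis and acinar injury, 0.674 for immediate early genes, and 0.874 for acinar enzymes, beta cell and mesenchyme. Fry gave 0.253 for S phase, 0.260 for G2 and M phase and adipocyte, 0.292 for endothelium and cholesterol synthesis, 0.0748 for PI3K, 0.341 for immediate early genes and acinar injury, 0.450 for beta cell, and 0.654 for acinar enzymes and mesenchyme. Acinar injury was not called with DESeq2's size factors (0.0510), upper-quartile factors (0.0684), enzymes left out (0.0503), the 1 CPM filter (0.0545), limma-voom (0.233), the erythroid covariate (0.0538) or the scaled table (0.133). In limma-voom, acinar enzymes (0.0702) and beta cell (0.0639) lost the call, while macrophage (0.0467) and erythroid (0.0191) lists gained it, both lower. With the length offset, beta cell (0.0777) and mesenchyme (0.0730) lost it. In the scaled table, acinar enzymes and mesenchyme (0.133 each) and beta cell (0.159) lost it. With the erythroid covariate, acinar enzymes (0.135) and immediate early genes (0.0538) lost it, and acinar secretory (0.0167) and mitochondrial (0.0279) lists were called higher. Without the erythroid-rich pair, mesenchyme lost it (0.283), macrophage (3.62e-08) and erythroid (1.53e-27) lists were called lower, and the intestine and liver list reversed to higher (0.00107), a setting that leaves out the library with liver transcripts.

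Over the leave-outs, adjusted p-values ran from 0.00537 to 0.478 for beta cell, 1.27e-09 to 0.533 for acinar enzymes, 0.00184 to 0.794 for mesenchyme, 0.00453 to 0.217 for immediate early genes and 2.41e-06 to 0.217 for acinar injury. Lists not called in the full data ran from 0.0191 to 0.979 (alpha, delta, PP and epsilon), 0.0433 to 0.959 (mesothelium), 0.0104 to 0.746 (acinar secretory), 8.27e-07 to 0.982 (macrophage), 0.0218 to 0.982 (lymphocyte), 4.22e-24 to 0.982 (erythroid), 0.0198 to 0.794 (nerve and glia), 0.0310 to 0.678 (TGF-beta) and 0.0166 to 0.853 (unfolded protein response, reversed to lower at 0.0315 without KO 2). No paired analysis was possible because the replicate numbers only follow sample order. At 20565387 reads or more per library, edgeR recovered 17.9% of simulated changes of 1.5 times and 90.9% of changes of 4 times, and depth was not varied, so its part in this limit stays open.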

Other observations

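The lists of FOXO, glucocorticoid and trypsinogen genes were written after gene-level results were seen. The cell cycle tests and the glucocorticoid test were chosen after the result was seen. The glucocorticoid test was first run on all 20 listed genes, where camera's p with its preset correlation was 1.4e-10. It was then repeated without the DESeq2 calls and without Zbtb16, Hif3a and Fam107a, which had been seen before the test. The 15 genes left were all part of the first run, so the repeat is not an independent test.

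The glucocorticoid-induced genes kept in the repeat had a median log2 fold change of 0.60 between KO and WT, with medians of 0.10 in KO 1, 0.53 in KO 2 and 1.0 in KO 3. Camera gave p = 6.2e-07 for them with its preset correlation, and the call was lost at p = 0.112 with an estimated correlation. Klf9, a glucocorticoid-induced transcription factor, stood at 62.9 ± 42.6 CPM in KO and 25.8 ± 1.501 CPM in WT, and Tsc22d3, which encodes GILZ, at 41.9 ± 14.2 against 27.1 ± 0.769 CPM. The metallothionein gene Mt1 stood at 341 ± 149 against 122 ± 89.5 CPM. Of 21 targets of FOXO transcription factors outside the DESeq2 calls, 16 were higher in KO (camera p = 0.0085, or p = 0.206 with an estimated correlation, where the call was lost). Map1lc3b, an autophagy gene, stood at 130 ± 33.5 against 95.3 ± 3.27 CPM and Klf15 at 27.8 ± 12.5 against 15.9 ± 2.89 CPM. Sesn3, the one of them with the smallest p, went the other way, at 62.5 ± 3.44 CPM in KO and 79.0 ± 8.64 CPM in WT, with every KO library below every WT library. Igfbp1 also had a lower mean in KO, which rested on 16.25 CPM in WT 1 against 0.200 to 1.18 CPM elsewhere. None of these passed the edgeR test over all genes.

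Fewer erythroid precursors, which divide, are a candidate cause of the lower cell cycle genes in KO, but with the erythroid level as a covariate the joint median log2 fold change of both lists was -1.15 (quartiles -1.37 and -0.90), which argues against them as the whole cause. Leaving out each library in turn gave a median from -1.54 to -0.82, so no single library carries the difference, although KO 1 shows it least. In the 10 splits of the 6 libraries, genes called over the 2 lists alone numbered 64 for the real split and 0 at most in the others, so 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. By size, the joint median was 1.08 for the real split and 0.711 at most in the others, for WT 1, KO 2 and KO 3 against the rest, where camera called both lists (adjusted p of 1.99e-15 or less). A difference of litter or stage between these mice stays open, as does an effect of the genotype.

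A lower insulin or nutrient signal, or a stress response, in the KO pups may underlie the FOXO and glucocorticoid calls, which rest on camera's preset correlation. The FOXO targets had a median log2 fold change of 0.20 and a camera p of 0.0085, or 0.057 without KO 3. Over the leave-outs their median ran from 0.126 (without WT 2) to 0.231 (without KO 1). Another split of the libraries gave a larger FOXO median, 0.207 against 0.195. Of the 15 glucocorticoid targets kept in the repeat 13 were higher, and the highest median of another split was 0.570 against 0.599 for the real one. Without KO 3 their median was 0.34, and an effect of handling or feeding on single pups was not tested.

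All 12 trypsinogen genes of the cluster on chromosome 6 had a lower mean in KO with each of the 3 scalings, with a median log2 fold change of -0.60. The digestive enzymes outside the cluster had a median of 0.17 (15 of 23 higher, quartiles -0.22 and 0.41), which argues against a smaller share of acinar RNA as the cause. A shift of reads among these near-identical genes could change single values. It would leave the sum of the cluster unchanged, and it could not lower all 12 genes. The summed CPM had a log2 ratio of -0.39 but overlapped between groups, so the sum alone could not decide whether the cluster fell as a whole. The sum was 85541 ± 9617 CPM in WT and 65442 ± 12074 CPM in KO, but KO 2 (77764 CPM) lay above WT 2 (75372 CPM).

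The 11 tested genes within 1 Mb of Mir216a were at the 42.9th percentile of gene windows by their mean absolute log2 fold change over SE, so the neighbourhood as a whole did not stand out. Ccdc85a, 173 kb away and chosen after its values were seen, stood at 8.18 ± 4.51 CPM in KO and 3.57 ± 0.506 CPM in WT and was called by DESeq2.

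With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Genes past the edgeR threshold numbered 0 for the real split and 1 at most in the others, and since any split reaches 0, this count says nothing about chance. Genes at an unadjusted p under 0.05 numbered 1996 and 1903, the latter for the split of WT 1, KO 1 and KO 2 against the rest, so 1 split gave as many. Called lists numbered 11 for the real split and 18 at most in the others. As many were given by 5 splits, the real one among them, so this count did not set the real split apart. The other splits mix the genotypes unevenly and still carry part of any genotype difference. They therefore cannot show how many lists camera calls without one.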
